A study of Mus musculus with 11 samples.

How the data were processed

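The data are Visium libraries of 11 mouse hemi-brain sections, cut at 10 µm from fresh frozen tissue in OCT, per the labels' protocols. Visium places a section on a slide of barcoded spots, so that each transcript carries the barcode of its spot. A spot can hold several cells of different types. Reads were processed with Space Ranger against mm10, per the submitters' processing notes, and the matrix headers name Space Ranger 2.0.0. The read aligner's settings and the gene annotation are not given in the sources used here. The authors deposited, for each section, a filtered matrix of UMI counts per gene and spot, with whole numbers and no normalization. The deposited spot positions, also unnormalized, were used to keep spots over tissue, and every deposited barcode lay over tissue. Each matrix listed the same genes, and 38 symbols were carried by more than 1 gene ID. Chromosomes and coordinates came from a gene table of GRCm38.p6, the assembly also called mm10, in which 26259 features were matched by symbol. Symbols are given as the files give them.

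Sections were grouped by the labels' sex and treatment into female control, female cuprizone, male control and male cuprizone. Female sections had the genotype label SRY minus and YMT minus, and male sections had both plus, where YMT is left as the labels write it. Replicate numbers were given in accession order and only name a section. The labels do not say that sections came from separate animals, so p-values measure the spread between these sections, which may be technical. File names carried the prefix FCG on 7 sections and LG (once as LG180) on 4, while most of the FCG sections had LG9 in their titles. The prefix was treated as a possible batch, and treatment was fitted again within each prefix as the only factor. The arms of those fits differ in sex, since LG holds 2 male cuprizone sections, 1 female control and 1 male control, so they are not the contrast averaged over the sexes. The report prints their values for most lists past the threshold and for some genes. No pair of sections was 1 library deposited again, since over 55 pairs of sections the lowest chi-square per gene was 3.7, above sampling noise.

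Totals ran from 5717125 to 82008197 UMIs per section, with 29172 spots in all. A count of 0 allows up to 3 counts, which is 0.0366 CPM in the deepest and 0.5247 CPM in the shallowest section. These limits cover counting error only and hold for whole sections, while regions hold fewer UMIs and have higher limits.

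Counts of all spots of a section were summed, since spots are not replicates. The sums were tested with edgeR 4.0.16 (glmQLFit and glmQLFTest, TMM scaling, filterByExpr) in R 4.3.3, with 1 coefficient per group and all 4 groups sharing 1 estimate of the spread. The contrasts were cuprizone against control averaged over the sexes, in females and in males, the sex by cuprizone interaction, and female against male in controls and under cuprizone. P-values were adjusted by the Benjamini-Hochberg method over the genes of each contrast, and a gene counted as past the threshold at an adjusted p under 0.05. Fold changes are on the log2 scale with a prior count of 2, with standard errors (SE), and levels are CPM after TMM scaling. The median log2 change over all genes stayed within 0.014 of 0 in every whole-section contrast.

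A total of 30 gene lists was fixed before the data were examined. They cover myelin and oligodendrocytes, stress, microglia, interferon, Toll-like receptor, antigen presentation, complement, astrocytes, cholesterol, neurons, immediate early genes, vessels, meninges, choroid plexus, ependyma, macrophages, lymphocytes, erythrocytes, the cell cycle, sex-linked, mitochondrial and hormone genes. Lists with at least 4 tested members, 29 in all, were tested with limma 3.58.1 camera at a preset correlation of 0.01 against the other genes. Each was tested again with camera and an estimated correlation, and with limma's fry, which asks whether the members move on balance 1 way and sets them against no other genes. Members were also counted after adjustment over the list alone. The lists share members, such as Cxcl10 in the interferon and astrocyte lists.

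Regions came from clustering all spots with leidenalg 0.10.2, igraph 0.11.9 and scikit-learn 1.9.0 under Python 3.11.15. Counts of each spot were scaled to the same total and log-transformed, and each gene was standardised within its section. Clustering used 2000 variable genes, 30 principal components, 15 neighbours and resolution 0.5. It left out 411 list genes, so that genes of the lists other than the neuronal ones did not set the regions. Clusters were named by region markers fixed beforehand, at a mean log2 fold of at least 1.0 with a marker among the 12 leading genes. A cluster below that fold whose leading gene had a log2 fold under 2.5 was given to its best neuronal marker set. Clusters of 6103, 3224 and 2977 spots, at marker folds of 0.38, 0.73 and 0.59, were named in this second way. Clusters of cortical and hippocampal neurons were joined. Counts were summed per section and region with at least 30 spots and tested by the same model. Shares of spots and differences between regions were tested with 2-sided exact permutation tests over all 200 rearrangements that keep the numbers of each sex.

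Genes named per whole-section contrast are the 10 largest rises and 10 largest falls past the threshold with a mean log2 CPM of at least 4 in which every section of 1 group lies above every section of the other. For the averaged contrast this had to hold in both sexes, and it was not asked of the interaction. Region fits name 5 per direction. Each list names up to 4 members per direction past the threshold, or else the 2 members with the smallest p. Xist, Ddx3y, Eif2s3y, Kdm5d, Uty, Kdm6a, Tlr7, Mbp, Gfap, Trem2, Apoe, C4b, Serpina3n, Cd68 and Cst7 were always reported. Some genes that meet this rule are not reported here. Genes under 3 counts in a whole-section library are given as counts or with those libraries raised to 3 counts. Values within regions are as fitted.

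The procedure was tested on simulated counts for the averaged contrast over 15611 genes with 200 changed. The changed genes were drawn only from those with a log2 of the mean CPM of at least 4, so low transcripts were not covered. Genes were simulated independently, with the fitted spread taken as true and no effect of the prefix. Under these conditions it recovered 100% of 2-fold changes in either direction, 90% of 1.5-fold rises and 92% of 1.5-fold falls, and 7.28% of calls were false. With no change simulated it made 0 calls in the averaged and interaction contrasts.

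The alternatives tried were median-of-ratios size factors, DESeq2 1.42.0, no filter, a filter of 50 counts in 3 sections, only the groups compared, the prefix or the depth as a covariate, mitochondrial and haemoglobin genes left out, thinning to 5717125 UMIs per section, and region-balanced sums tested with limma at a pseudocount of 1 CPM. Regions were also clustered at resolution 1.0, with all variable genes, and with a minimum of 100 spots. Each section was left out in turn. Fits within each prefix, for the sexes under cuprizone within FCG only, and without the 2 sections whose sex transcripts conflict with their labels, were added after the data were seen. Tissue images were not used here, no cell-type makeup was estimated, and samples with tau pathology were not analysed here.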

Results

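Visium, a spatial assay that reads transcripts from barcoded spots under a tissue section, was used on 11 mouse hemi-brain sections. Mice were controls or had received cuprizone for 5 weeks. Cuprizone is a copper chelator that kills oligodendrocytes and strips myelin from axons. The labels gave 2 female control, 3 female cuprizone, 3 male control and 3 male cuprizone sections. The series concerns how sex, hormones and sex chromosomes bear on this demyelination, and its title names Tlr7, an X-linked sensor of single-stranded RNA. Totals were 8616533 and 82008197 UMIs in the female controls and 59710558, 14561451 and 10041870 in the female cuprizone sections. Male controls held 5758399, 5717125 and 65515800 UMIs, and male cuprizone sections 11467751, 46780673 and 51891632. Median UMIs per spot ran from 1864 to 30578. The 4 sections with the LG prefix were female control 2, male control 3 and male cuprizone 2 and 3, and the other 7 had the prefix FCG. No female cuprizone section had the LG prefix.

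Transcripts of the sex chromosomes were read first, to set each library beside its label. Xist, the RNA that coats the inactive X, had 1815 counts (22.1 CPM) in female control 2 and 2956, 500 and 329 counts in the female cuprizone sections. It had 0 counts in the library labelled female control 1, which at that depth allows up to 0.3482 CPM. That library held 319 counts of Ddx3y (37 CPM), 230 of Eif2s3y, 114 of Kdm5d and 68 of Uty, all genes of the Y chromosome. In the libraries labelled male, Ddx3y had 217 counts or more. The library labelled male control 3 held 205 counts of Xist (3.13 CPM) beside 1905 of Ddx3y (29.1 CPM), while the other libraries labelled male had at most 1 count of Xist. Among the other female-labelled libraries Ddx3y had at most 2 counts and Kdm5d at most 7. Thus 1 of 5 libraries labelled female held Ddx3y above the limit of 3 counts, and 1 of 6 labelled male held Xist above it. Sry, Usp9y and Zfy1 had 0 counts in every library. Groups below follow the labels, and each contrast that involves female controls rests on 2 libraries of which 1 conflicts with its label.

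**Figure D1:**
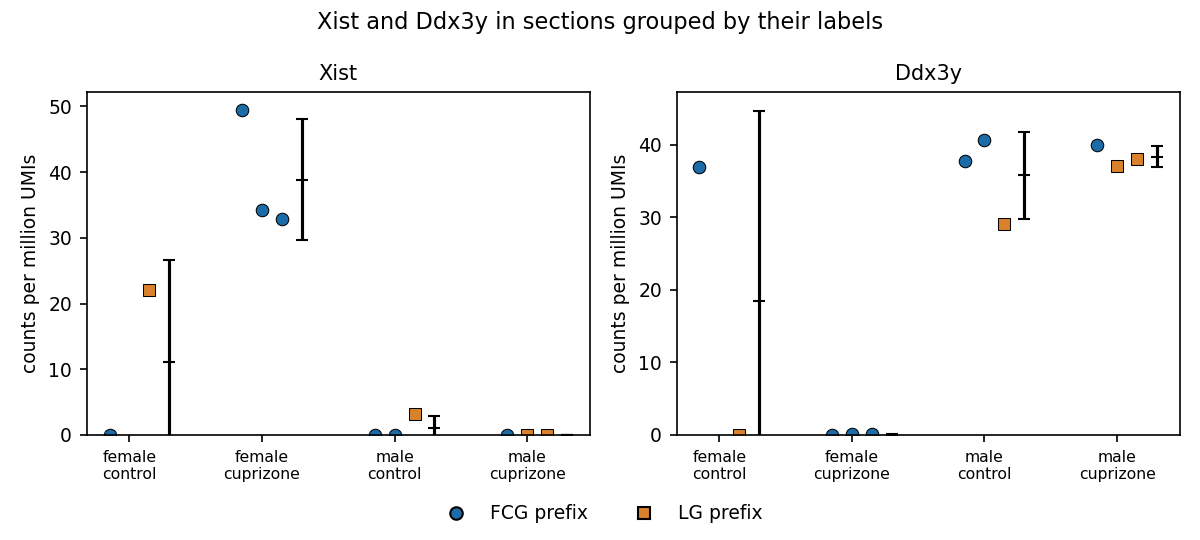
Xist and Ddx3y in CPM of all UMIs for each section, by group. Each point is 1 section, with blue circles for the FCG prefix and orange squares for the LG prefix, and bars give the mean and SD. The library labelled female control 1 sits at 0 for Xist and at 37 for Ddx3y.

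The first comparison asked what 5 weeks of cuprizone did to the section as a whole, averaged over the sexes. Transcripts of mature oligodendrocytes fell. Mbp, which encodes myelin basic protein (chromosome 18, 82475091 to 82585637, mm10), went from 2540 ± 90.8 CPM in controls (SD, n = 5) to 1470 ± 279 under cuprizone (n = 6), a log2 change of -0.81 (SE 0.08, adjusted p = 0.00048). Mal, a membrane protein of myelin, went from 188 ± 30.6 to 93.4 ± 21.5 CPM (-1.05, SE 0.11, adjusted p = 0.00078). Atf5 (chromosome 7, 44812256 to 44816658), a transcription factor of the stress response to unfolded proteins and amino acid shortage, rose from 12.1 ± 0.807 to 43.7 ± 12.3 CPM (1.81, SE 0.12, adjusted p = 5.1e-06). Nupr1, a stress-induced chromatin regulator on chromosome 7 (126623246 to 126625470), rose from 14.8 ± 2.24 to 48.5 ± 12.1 CPM (1.64, SE 0.1, adjusted p = 5.1e-06).

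In all 47 of 15611 genes passed the threshold, 9 higher and 38 lower, and 1030 had an unadjusted p under 0.05. Cdkn1a, which encodes the cell cycle inhibitor p21, rose by 0.99 (SE 0.13, adjusted p = 0.0048). Falls of the myelin group included Ppp1r14a at -1.14, Anln at -1.06, Ugt8a, which makes the galactolipids of myelin, at -0.93, Fa2h at -0.88 and Cldn11, the tight junction protein of myelin, at -0.88, with adjusted p from 0.00048 to 0.0083. As the naming rule asks, every section of 1 treatment lay above every section of the other in both sexes for these genes. The calls of Atf5, Nupr1, Cdkn1a, Ppp1r14a, Mal, Ugt8a and Mbp were kept under every alternative run. Fits within a prefix compared treatments without regard to sex, so that they are not the contrast averaged over the sexes. The LG fit set 2 male cuprizone sections against 1 female and 1 male control, and the FCG fit 3 female and 1 male cuprizone sections against 1 control labelled female and 2 male ones. Every FCG control held Ddx3y and no Xist, while the 3 female FCG cuprizone sections held Xist. Treatment within FCG is thus largely confounded with the sex chromosomes. Within the FCG and LG prefixes, the changes were 2.04 and 1.3 for Atf5, 1.98 and 1.15 for Nupr1, -0.87 and -0.64 for Mbp, and -1.1 and -0.85 for Mal. The count depended on single libraries and was 20 without male control 3, 25 without female control 2, 25 without female cuprizone 3 and 30 without male cuprizone 2. It was 76 with the prefix as a covariate and 12 without both sections whose sex transcripts conflict with their labels. The fits within a prefix called 24 genes in FCG and 103 in LG.

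**Figure D2:**
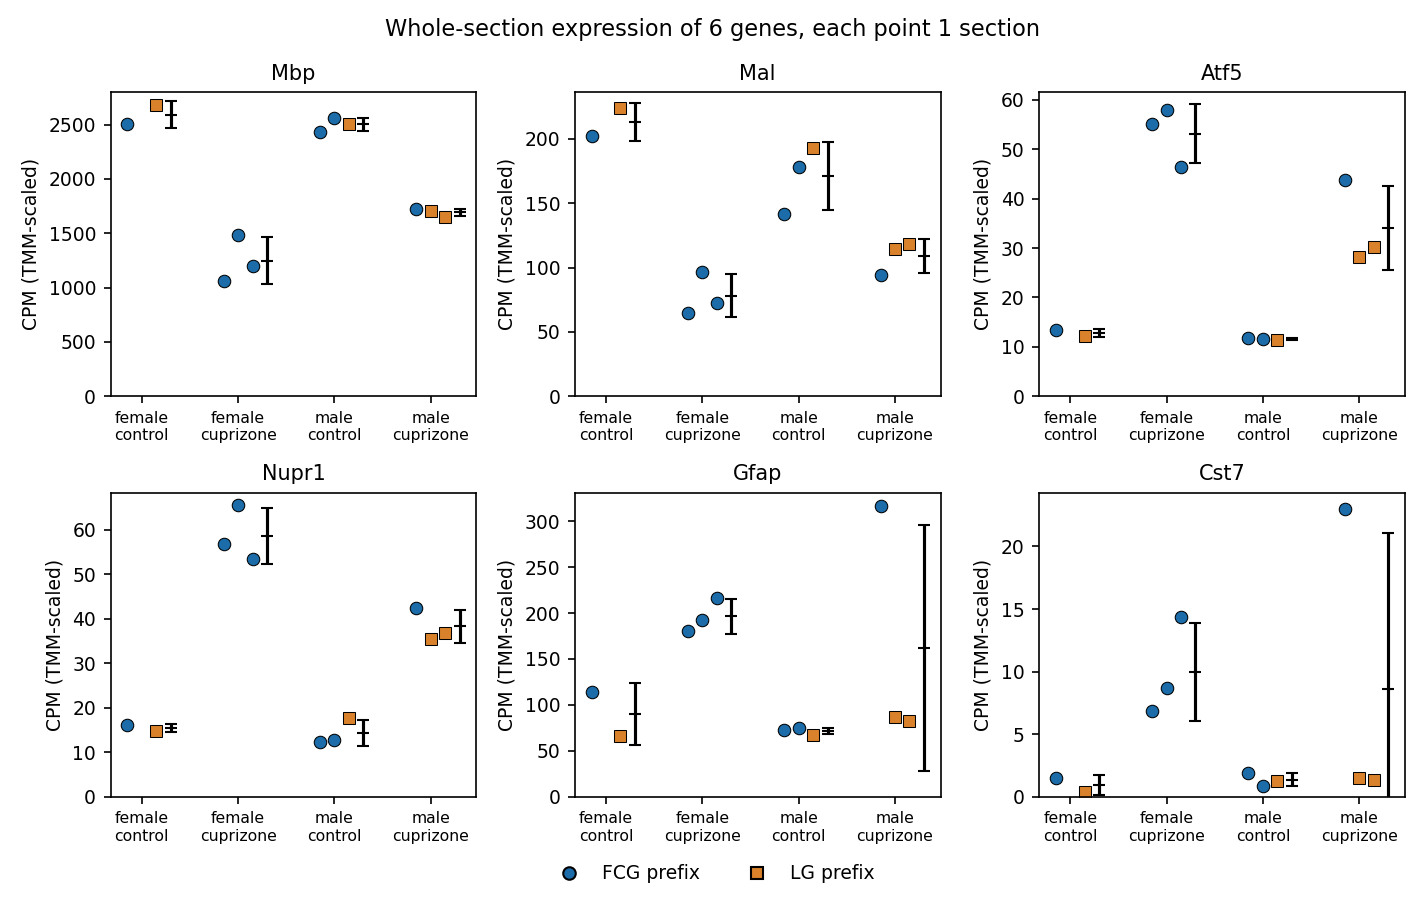
TMM-scaled CPM of Mbp, Mal, Atf5, Nupr1, Gfap and Cst7 for each section, by sex and treatment. Each point is 1 section, with blue circles for the FCG prefix and orange squares for the LG prefix, and bars give the mean and SD. The cuprizone sections lie below the controls for Mbp and above them for Atf5 and Nupr1, while Gfap and Cst7 spread widely among the male cuprizone sections.

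Of the 31 tested members of the myelin and mature oligodendrocyte list, 11 fell and 0 rose over all genes, and 24 fell and 1 rose when adjusted over the list alone. The list's median was -0.5 (camera adjusted p = 8e-37, adjusted p = 0.059 with an estimated correlation, fry adjusted p = 0.011). The integrated stress response list, which holds targets of Atf4, had 4 of 17 members higher over all genes and 11 adjusted over the list alone, with a median of 0.27 (camera adjusted p = 1.1e-13, adjusted p = 0.059 with an estimated correlation, fry adjusted p = 0.0026). Its risen members were Atf5, Nupr1, Gdf15, a secreted stress cytokine, and Trib3, a pseudokinase of the same response. Gdf15 had 1, 39, 1, 2 and 13 counts in the controls and 366, 93, 43, 19, 42 and 95 under cuprizone, in the order of the totals above (adjusted p = 0.00048). Trib3 had 5, 71, 7, 0 and 61 against 375, 90, 63, 47, 84 and 85 counts (adjusted p = 0.012). With libraries under 3 counts raised to that limit, their changes were at least 2.82 and 2.29 on the log2 scale of CPM. In the cholesterol synthesis list 0 of 24 members passed over all genes and 13 fell adjusted over the list alone, with a median of -0.23 (camera adjusted p = 1.4e-16, adjusted p = 0.059 with an estimated correlation, fry adjusted p = 0.011), and its leading members Cyp51 and Sc5d stood at -0.27 and -0.32. Its median was -0.37 within the FCG sections (camera adjusted p = 8.1e-19) and -0.05 within the LG sections (camera adjusted p = 0.32). The myelin list stood at -0.52 and -0.42 within the prefixes and the stress list at 0.34 and 0.14. The oligodendrocyte precursor and newly formed oligodendrocyte list had 0 of 16 members past the threshold over all genes, and 2 higher and 1 lower adjusted over the list alone, with a median of 0.02 (camera adjusted p = 0.79). Its leading members Enpp6 and Olig2 stood at -0.74 and 0.29. The cholesterol efflux and lipid storage list had 0 members past the threshold over all genes and 1 lower adjusted over the list alone, with a median of 0.04 (camera adjusted p = 0.42), where Plin3 stood at -0.48 and Lpl at 0.69.

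Microglial and astrocyte genes had higher means under cuprizone, with a wide spread that followed the file prefix among the cuprizone sections. Among controls the library labelled female control 1 stood apart, in CPM of all UMIs. It had 114 for Gfap and 36.2 for C4b, against 64.7 to 74.2 and 14.5 to 20.3 in the other controls. It was also highest for Serpina3n, Trem2 and Apoe, but not for Cd68 and Cst7. Gfap, the intermediate filament of astrocytes, had 78.9 ± 19.8 CPM in controls and 179 ± 87.5 under cuprizone (1.16, SE 0.31, adjusted p = 0.21). Cst7, a cathepsin inhibitor of activated microglia, had 1.19 ± 0.582 and 9.29 ± 8.28 CPM (3.26, SE 0.82, adjusted p = 0.16). Within the FCG sections both passed, at 1.37 (adjusted p = 0.024) for Gfap and 3.14 (adjusted p = 0.029) for Cst7. Every FCG control held Y-linked transcripts, so that fit does not separate treatment from sex chromosomes. Within the LG sections Gfap and Cst7 stood at 0.34 (adjusted p = 0.05) and 0.81 (adjusted p = 0.64). Both also passed over all prefixes without male cuprizone 1, at 0.7 for Gfap and 2.06 for Cst7. Serpina3n stood at 1.13, C4b at 0.87, Cd68 at 0.7, Trem2 at 0.6 and Apoe at 0.29, with adjusted p from 0.47 to 0.8. Without male cuprizone 1 they stood at 0.59, 0.44, 0.41, 0.26 and 0.14.

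The disease-associated microglia list had 0 of 26 members past the threshold over all genes and 11 higher adjusted over the list alone, with a median of 0.63 (camera adjusted p = 5.5e-12, adjusted p = 0.29 with an estimated correlation, fry adjusted p = 0.2). The chemokines Ccl4 and Ccl3 led it, Ccl4 at 2.65 and Ccl3 at no less than 2.41 with the library under 3 counts raised to that limit. Its median was 0.79 within the FCG sections and 0.1 within the LG sections, where camera gave adjusted p = 0.096. Over all prefixes it was 0.26 without male cuprizone 1. The reactive astrocyte list had 1 of 21 members higher over all genes and 9 adjusted over the list alone, with a median of 0.11 (camera adjusted p = 9.8e-05, adjusted p = 0.29 with an estimated correlation). Its medians were 0.47 and 0.01 within the prefixes, where the LG value had camera adjusted p = 0.68. The pooled median of that list was 0.07 without male cuprizone 1 and 0.42 without the library labelled female control 1. The member that rose was Cxcl10, an interferon-induced chemokine that also belongs to the interferon response list (5, 41, 0, 6 and 21 counts in controls and 73, 117, 41, 92, 205 and 94 under cuprizone, at least 2.75 by the same bound, adjusted p = 0.046). That list had 1 of 30 members higher over all genes and 6 adjusted over the list alone, with a median of 0.51 (camera adjusted p = 1.6e-12, adjusted p = 0.29 with an estimated correlation) and medians of 0.56 and 0.24 within the prefixes. The homeostatic microglia list had 0 members past the threshold either way and a median of 0.14 (camera adjusted p = 0.082). It went opposite ways within the prefixes, at 0.25 in FCG (camera adjusted p = 6.8e-05) and -0.13 in LG (camera adjusted p = 0.0026). The homeostatic astrocyte list also had 0 members past the threshold either way, at 0.04 (camera adjusted p = 0.26).

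Tlr7 had 3.07 CPM in controls and 3.69 under cuprizone (0.35, SE 0.28, adjusted p = 0.96), on 15 to 190 counts per library. This change was -0.06 without female control 2 and 0.71 without the library labelled female control 1. The Toll-like receptor signalling list had 0 of 17 members past the threshold over all genes or over the list alone, with a median of 0.19 (camera adjusted p = 0.0077, adjusted p = 0.29 with an estimated correlation), led by Slc15a4 at -0.26 and Cd14 at 0.82. Within the prefixes its median was 0.29 and 0.07, where the LG value had camera adjusted p = 0.19. The antigen presentation list had 0 of 15 past the threshold either way, with a median of 0.4 (camera adjusted p = 7.3e-05, adjusted p = 0.39 with an estimated correlation), and its median was 0.51 within the FCG and -0.04 within the LG sections and 0.13 without male cuprizone 1. The complement list had 0 of 14 over all genes and 1 higher adjusted over the list alone, with a median of 0.49 (camera adjusted p = 0.0094, adjusted p = 0.39 with an estimated correlation) and 0.72 and -0.02 within the prefixes. It was 0.22 without male cuprizone 1, and the call was lost without female control 2 or male control 2.

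None of the lists of structures other than the parenchyma passed with an estimated correlation. The choroid plexus list had 3 of 10 members lower over all genes and 10 adjusted over the list alone, with a median of -1.31 (camera adjusted p = 1e-15, adjusted p = 0.16 with an estimated correlation). Ttr, the thyroxine carrier of the choroid plexus, went from 8000 ± 6490 to 2280 ± 495 CPM (-1.55, SE 0.27, adjusted p = 0.031), and Folr1 and Ecrg4 fell by 1.67 and 1.25. Enpp2, which encodes autotaxin and is among the leading genes of the choroid plexus cluster, fell by 1.1 on the log2 scale (SE 0.2, adjusted p = 0.035). The region-balanced sums ended the calls of Ttr and Ecrg4, at -0.9 and -0.56. Of the 11 fits that each left out 1 section, 8 lost the call of Ttr, 8 that of Enpp2 and 5 that of Ecrg4. The list's median was -1.81 within the FCG and -1.04 within the LG sections. Choroid plexus spots made up 1.069 ± 0.696% of the control and 0.484 ± 0.155% of the cuprizone sections (exact permutation p = 0.155). Male control 2 and 3 held 48 and 45 such spots, and every other section at most 18. Medians were -0.42 for the ependymal list (2 of 9 lower adjusted over the list alone; camera adjusted p = 4.6e-05, adjusted p = 0.29 with an estimated correlation) and -0.35 for the meningeal fibroblast list (2 of 11 lower; camera adjusted p = 0.0005, adjusted p = 0.29 with an estimated correlation), with 0 members of either past the threshold over all genes. Within the FCG and LG sections they were -0.62 and -0.11 for ependymal and -0.53 and -0.2 for meningeal fibroblast, and the LG values had camera adjusted p = 0.078 and 0.15. The erythrocyte list had 0 of 5 members past the threshold either way and a median of -0.38 (camera adjusted p = 0.008, adjusted p = 0.39 with an estimated correlation), and its median was -0.82 within the FCG and 0.54 within the LG sections, whose arms differ in sex. It lost its call in 3 of 11 fits that each left out 1 section, at -0.18 without the library labelled female control 1.

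The remaining lists had 0 members past the threshold over all genes. The pan-neuronal and excitatory neuron list had a median of -0.03 (camera adjusted p = 0.22) and the inhibitory neuron list 0.04, where the test pointed down (camera adjusted p = 0.65). The immediate early genes list stood at -0.39 (camera adjusted p = 0.0031, adjusted p = 0.47 with an estimated correlation) and the endothelial list at -0.07 (camera adjusted p = 0.045, adjusted p = 0.29 with an estimated correlation). Without female control 2 the immediate early genes list was at -0.04 and lost its call, as it did without male cuprizone 1, at -0.25, and the endothelial call was lost in 7 of 11 fits that each left out 1 section. Within the FCG and LG sections the lists stood at -0.43 and -0.11 and at -0.02 and -0.17, where the LG value of immediate early genes had camera adjusted p = 0.074 and the FCG value of the endothelial list 0.62. Medians were 0.03 for the mural cell list, -0.08 for border macrophage, -0.04 for lymphocyte, 0.05 for cell cycle, -0.02 for mitochondrially encoded, 0.07 for sex hormone receptors and steroid enzymes, and 0.11 for X-linked inactivation escape, with camera adjusted p from 0.095 to 0.72. The mitochondrially encoded list stood at -0.13 within the FCG sections (camera adjusted p = 0.011) and 0.14 within the LG sections (camera adjusted p = 0.00051). The X inactivation list, with 3 tested members, was not tested as a set and had a median of 0.16 and a mean of -0.85. The Y-linked list had 4 members lower adjusted over the list alone (camera adjusted p = 0.0067, adjusted p = 0.38 with an estimated correlation). With libraries under 3 counts raised to that limit its median was -1.35, and the female controls here include the library with Y-linked transcripts. Of the 29 lists tested, 16 passed with the preset correlation, 3 with fry and 0 with an estimated correlation.

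The next comparison asked whether cuprizone acted differently in females and males. In females Mbp went from 2590 ± 123 (n = 2) to 1250 ± 218 CPM (n = 3; -1.05, SE 0.12, adjusted p = 0.0021). In males Mbp went from 2500 ± 62.5 to 1690 ± 36.6 CPM (n = 3 each), which did not pass over all genes (adjusted p = 0.15). Atf5 rose in females from 12.8 ± 0.808 to 53.2 ± 6.03 CPM (2.07, SE 0.18, adjusted p = 0.00012) and in males from 11.6 ± 0.249 to 34.1 ± 8.5 CPM (1.54, SE 0.16, adjusted p = 0.0019). Nupr1 rose by 1.94 in females (adjusted p = 7.9e-05) and 1.34 in males (adjusted p = 0.0019). Ide, the insulin-degrading enzyme, rose in males from 29.8 ± 1.09 to 45 ± 3.04 CPM (0.58, SE 0.08, adjusted p = 0.04) and had 29.5 and 30.2 CPM in the female groups. The male call of Ide was lost in 10 of the 11 fits that each left out 1 section.

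In females 20 genes passed, 5 higher and 15 lower, and in males 4, all higher. The fourth male gene, named after its values were seen, was Col5a3, a collagen chain, at 1.74 (adjusted p = 0.012), which also rose in females by 3.29. Female falls among myelin genes included Ppp1r14a at -1.63, Mal at -1.45, Anln at -1.4, Fa2h at -1.24, Ugt8a at -1.16, Cldn11 at -1.16, Cmtm5 at -0.86 and Gamt, which makes creatine, at -0.77, with adjusted p from 0.0021 to 0.034. Of the 11 fits that each left out 1 section, 7 lost the female call of Gamt, 5 that of Cmtm5, 3 that of Cldn11 and 1 that of Anln. No gene passed the test of the interaction, the difference between the sexes itself, in edgeR, where 439 had an unadjusted p under 0.05, while DESeq2 called 10 and edgeR without the filter on low counts 12. The interaction was 0.6 (SE 0.2) for Nupr1, -0.49 (SE 0.17) for Mbp, -0.8 (SE 0.23) for Mal, -0.03 (SE 0.6) for Gfap and -0.29 (SE 0.56) for Tlr7, each with adjusted p = 1, and -0.55 (SE 0.13, adjusted p = 0.81) for Ide. Across the 8008 genes with a mean log2 CPM of at least 4, the female and male changes correlated with r = 0.169 and 4120 had the same sign, where genes are not independent replicates. The female count was 11 without the library labelled female control 1, 12 without male cuprizone 3, 13 without female cuprizone 3, 31 without female cuprizone 2 and 55 without male cuprizone 1. The male count was 2 without male cuprizone 3, 7 without female cuprizone 1 and 25 without male control 1, and the interaction count was 9 without male control 3 and 6 without female control 2 or male cuprizone 1.

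Of the myelin and mature oligodendrocyte list, 10 members fell in females over all genes and 27 adjusted over the list alone, with a median of -0.72 (adjusted p = 0.074 with an estimated correlation, fry adjusted p = 0.015). In males 0 fell over all genes and 11 adjusted over the list alone, with a median of -0.28 (camera adjusted p = 1.6e-12, adjusted p = 0.37 with an estimated correlation). The interaction of the list had a median of -0.46, with 0 members past the threshold over all genes and 7 lower adjusted over the list alone (camera adjusted p = 6.1e-14, adjusted p = 0.5 with an estimated correlation, fry adjusted p = 0.51). The integrated stress response list had 4 members higher in females and 2 in males over all genes (7 and 6 adjusted over the list alone), and an interaction median of 0.11 (camera adjusted p = 0.13). The interferon response list had a median of 0.26 in females and 0.8 in males, where 6 members rose adjusted over the list alone, and adjusted p = 0.75 and 0.34 with an estimated correlation. Its female median was -0.17 without female control 2. The disease-associated microglia list stood at 0.65 in females and 0.52 in males (adjusted p = 0.39 and 0.46 with an estimated correlation), with an interaction of 0.18 (camera adjusted p = 0.12). Its male median was 0.02 without male cuprizone 1 (camera adjusted p = 0.97). All 3 female cuprizone sections had the FCG prefix, and 2 of the 3 male ones had LG. The only female control with Xist had the LG prefix. No female control therefore matched the female cuprizone sections in both prefix and Xist. Erythrocyte transcripts moved with these groups. The erythrocyte list's median was -1.41 in females (5 lower adjusted over the list alone) and 0.78 in males (4 higher), and haemoglobin took 0.271 and 0.171% of UMIs in the female controls and 0.072 to 0.089% in the female cuprizone sections. Male sections had 0.085 to 0.162% as controls and 0.133 to 0.261% under cuprizone.

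A further comparison set female against male sections within each treatment. In controls 0 genes passed in edgeR, 459 had an unadjusted p under 0.05 and DESeq2 also called 0, while 6 passed without the library labelled female control 1, 1 without male control 3 and 11 without both. Kdm6a, an X-linked demethylase that escapes inactivation, had 14 ± 3.9 CPM in female and 10.4 ± 1.16 in male controls (0.45, SE 0.16, adjusted p = 1), and Tlr7 3.03 ± 2.09 and 3.1 ± 0.669 CPM (-0.24, SE 0.44, adjusted p = 1). The female mean of Tlr7 joins 4.51 CPM in the library labelled female control 1, which held no Xist, and 1.55 in female control 2. Male controls had 2.62, 3.86 and 2.81 CPM. In CPM of all UMIs, Kdm6a had 11.3 and 16.8 in the female and 10.6, 9.1 and 10.9 in the male controls. These means therefore do not compare females with Xist to males, and only 1 female control held Xist. The endothelial list stood 0.32 higher in females in the median (camera adjusted p = 3.2e-05, adjusted p = 0.056 with an estimated correlation, fry adjusted p = 0.045) and the choroid plexus list at -1.05 (9 members lower adjusted over the list alone; adjusted p = 0.52 with an estimated correlation), with 0 members of either past the threshold over all genes. These were 0.16 without male control 3 and -0.55 without male control 2.

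Under cuprizone 14 genes differed between the sexes, 9 higher and 5 lower in females. Xist was among them (adjusted p = 0.023), at 8.59 with libraries under 3 counts raised to that limit. No Y-linked gene was, though the same bound put Ddx3y at -8.04, Eif2s3y at -7.48, Kdm5d at -5.91 and Uty at -5.2, with adjusted p from 0.082 to 0.13. Ddx3y had 0, 1 and 1 counts in the female and 458, 1734 and 1976 in the male cuprizone sections. The spread shared by all groups includes the female controls, which held 319 and 2 counts of Ddx3y, and such a gap widens it. These missed calls therefore do not speak against a sex difference. Ddx3x, an X-linked helicase that escapes inactivation, had 170 ± 3.46 CPM in females and 108 ± 13.5 in males (0.66, SE 0.11, adjusted p = 0.043). Olig2, a transcription factor of the oligodendrocyte lineage, had 41.2 ± 2.63 and 28 ± 1.59 CPM (0.55, SE 0.09, adjusted p = 0.041), and Arap2 59.7 ± 4.26 and 37.9 ± 3.95 CPM (0.66, adjusted p = 0.031). Lower in females were Tmsb4x, which encodes the actin-binding thymosin beta 4, with 2110 ± 125 against 4570 ± 295 CPM (-1.11, SE 0.14, adjusted p = 0.023), Frmpd4 with 37.7 ± 0.682 against 73.6 ± 9.93 (-0.97, adjusted p = 0.041), Hccs with 21.5 ± 1.4 against 41 ± 6.74 (-0.94, adjusted p = 0.041), Ide at -0.57 (adjusted p = 0.031) and Flywch2 at -0.53 (adjusted p = 0.041). Tmsb4x, Frmpd4 and Hccs lie within chromosome X 167207093 to 169320374 of mm10. Among the 7 genes of that segment followed here, all 7 were lower in females with a median of -0.88, including Tlr7 at -0.53 (2.93 ± 0.281 against 4.46 ± 1.82 CPM, SE 0.35, adjusted p = 0.55), which did not pass alone. The segment was chosen after its values were seen, and the 13 genes beside it had a median of 0.05. Kdm6a stood at 0.71 (SE 0.14, adjusted p = 0.086).

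The X-linked inactivation escape list had 1 of 9 members higher in females under cuprizone over all genes and 3 adjusted over the list alone, with a median of 0.27 (camera adjusted p = 0.0003, adjusted p = 0.18 with an estimated correlation, fry adjusted p = 0.013). The erythrocyte list was at -1.43 (5 lower adjusted over the list alone; adjusted p = 0.25 with an estimated correlation). The number of genes called between the sexes under cuprizone depended on single libraries. It was 0 without female cuprizone 3, male cuprizone 2 or male cuprizone 3, 1 without female cuprizone 1, 2 without male control 1, 6 without male control 2 and 8 without female cuprizone 2. It was 28 without male control 3, 38 without female control 2, 45 without the library labelled female control 1 and 169 without male cuprizone 1. Among the named genes, fits that each left out 1 section lost the call of Tmsb4x in 4 of 11, of Arap2 in 6 and of Ddx3x, Olig2, Frmpd4, Hccs, Ide and Flywch2 in 7. With the prefix as a covariate the count was 2, Tmsb4x among them. Within the FCG sections, in a fit added after the data were seen, it was 20, 2 higher and 18 lower, where 3 female cuprizone sections stood against 1 male one, whose spread was taken from the other groups. There Tmsb4x, Frmpd4, Hccs and Ddx3x stood at -0.99, -0.71, -0.62 and 0.48.

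**Figure D3:**
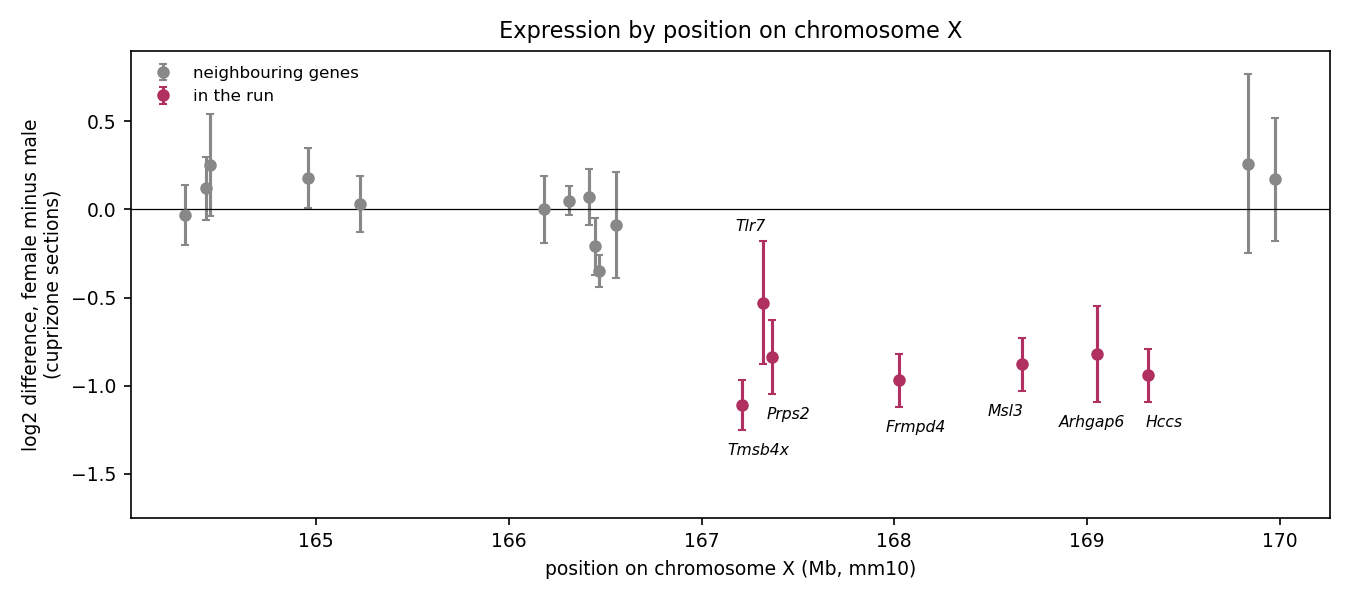
Difference between female and male cuprizone sections in log2, with SE bars, against the position in Mb on chromosome X (mm10). Red points are the 7 genes of the segment and grey points their neighbours. The red points lie below 0, with a mean of -0.87.

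Spots fell into regions by the naming rule above, and only the smallest cluster of cortex and hippocampus reached the marker fold of 1.0. White matter held 3724 spots, with Mal and Apod among its leading genes. Clusters of cortex and hippocampus held 6103, 3224, 2977 and 848 spots, hypothalamus 5053, thalamus 4172 (Prkcd, Tcf7l2) and striatum 2148 (Penk, Adora2a). Small clusters were meninges (297 spots) and choroid plexus, and 411 spots led by Six3 and Pvalb stayed unnamed. White matter spots made up 13.066 ± 1.285% of the cuprizone sections (n = 6) and 12.412 ± 3.443% of the controls (n = 5), with an exact permutation p = 0.845. No region's share passed after adjustment (adjusted p = 0.92 for treatment). Shares did differ by prefix, which was not tested. Hypothalamus took 19.453 to 22.933% of spots in the LG and 11.981 to 17.504% in the FCG sections. Striatum took 8.787 to 12.543% and 4.096 to 7.604%, and white matter 8.346 to 11.618% and 13.037 to 17.297%. What was cut is thus not balanced between the prefixes.

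Within white matter the stress genes rose from low control levels. White matter held only 468328 UMIs in female control 1, 224226 in male control 1 and 312800 in male control 2. Control levels of these genes there rest on few counts, so the sizes of the rises are uncertain. Cdkn1a went from 12.7 ± 8.32 to 91 ± 36.5 CPM (3.02, SE 0.25, adjusted p = 3.1e-08), Nupr1 from 13.7 ± 3.46 to 98.3 ± 28.5 (2.99, SE 0.22, adjusted p = 2.9e-09) and Atf5 from 22.8 ± 8.26 to 130 ± 43.7 (2.5, SE 0.22, adjusted p = 6.8e-08). Mthfd2, a mitochondrial folate enzyme, and Cebpg, a partner of Atf4, rose by 1.33 and 1.27. Falls included Klk6, a protease of oligodendrocytes, at -1.39 (SE 0.19, adjusted p = 9.8e-05), Prrg1 at -1.34, Mal at -1.23 and Gamt at -1.2. Mbp fell by 0.86 on the log2 scale (SE 0.14, adjusted p = 0.00043). In all 237 of 10011 genes passed, 45 higher and 192 lower. The count was 62 without female control 2, 115 without male control 3, 143 without female cuprizone 1 and 150 without male control 2, and 84 and 16 within the FCG and LG sections.

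The myelin and mature oligodendrocyte list had 21 of 31 members lower in white matter over all genes and 29 adjusted over the list alone, with a median of -0.66 (camera adjusted p = 1.7e-31, adjusted p = 0.053 with an estimated correlation, fry adjusted p = 0.0042). The integrated stress response list had 8 of 17 higher over all genes, and 13 higher and 1 lower adjusted over the list alone, with a median of 0.97 (camera adjusted p = 2.5e-15, adjusted p = 0.053 with an estimated correlation, fry adjusted p = 0.002). The cholesterol synthesis list had 4 of 22 lower over all genes and 8 adjusted over the list alone, with a median of -0.34 (camera adjusted p = 2.7e-10), and its call held with an estimated correlation (adjusted p = 0.022). Idi1, Insig1, Hmgcs1 and Msmo1 were the members that fell, by 0.96, 0.59, 0.56 and 0.56 on the log2 scale. The disease-associated microglia list had 0 of 25 past the threshold over all genes and 17 higher adjusted over the list alone, with a median of 0.8 (camera adjusted p = 0.0011, adjusted p = 0.78 with an estimated correlation). The interferon response list had 1 of 21 higher over all genes and 12 adjusted over the list alone, with a median of 0.91 (camera adjusted p = 1.9e-05, adjusted p = 0.41 with an estimated correlation). In white matter Gfap stood at 0.63 (adjusted p = 0.2), Cst7 at 2.45 (adjusted p = 0.11) and Tlr7 at 0.84 (adjusted p = 0.58). Over the whole section, male control 1 and 2 held 11 and 5 counts of Cst7 and 15 and 22 of Tlr7. White matter holds only a part of these, so the values of Cst7 and Tlr7 rest on very few counts. They are as fitted and are no bounds.

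By sex, 277 genes passed in female white matter, 57 higher and 220 lower, and 8 in male white matter, 6 higher and 2 lower. Nupr1 rose by 3.34 in females and 2.64 in males and Cdkn1a by 3.49 and 2.55. The interaction passed for 4 genes, all haemoglobins, Hbb-bs, Hba-a1, Hba-a2 and Hbb-bt, at -2.92 to -2.74. Counts of the near-identical haemoglobin copies cannot be separated with certainty. For myelin the interaction median was -0.74, with 0 members over all genes and 24 lower adjusted over the list alone, in the myelin and mature oligodendrocyte list (camera adjusted p = 4.2e-16, adjusted p = 0.37 with an estimated correlation). The female count was 29 without female control 2, 113 without female cuprizone 1, 150 without female cuprizone 3 and 536 without male cuprizone 1. The male count was 0 without male control 3, 3 without male control 2 and 4 without male cuprizone 3, where edgeR had given an unadjusted p under 0.05 for 436 genes with all sections and DESeq2 had called 7. The interaction count was 52 without male cuprizone 1.

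Stress and myelin genes were also among the calls of other regions. In cortex and hippocampus 33 genes passed, led by Atf5 at 1.79 (SE 0.11, adjusted p = 1.2e-06) and Nupr1 at 1.5, with Ppp1r14a and Mal at -1.58 and -1.46. In the striatum 70 passed, with Atf5 at 2.11 (SE 0.15, adjusted p = 2e-09), Nupr1 at 1.9, Cdkn1a at 1.74 and Gfap at 1.3 (SE 0.22, adjusted p = 0.0012) higher, and Ppp1r14a at -1.91, Fa2h at -1.8 and Mal at -1.73 (SE 0.11, adjusted p = 5.4e-10) lower. Gfap lost its striatal call without female control 2, at 0.99. In the striatum 22 of the 29 tested members of the myelin and mature oligodendrocyte list fell over all genes and 26 adjusted over the list alone, with a median of -0.95, and the call held with an estimated correlation (adjusted p = 0.018). In the thalamus 22 passed, including Ugt8a at -0.91 and Mbp at -0.79, and in the hypothalamus 3, among them Nupr1 at 1.48 and Atf5 at 1.43, which was lost as a call in 3 of 11 fits that each left out 1 section. Without male control 3 the counts were 12 in cortex and hippocampus, 4 in thalamus and 31 in striatum. In cortex and hippocampus 17 passed without female cuprizone 3 and 20 without female cuprizone 1, in thalamus 9 without female control 2 and 49 without the library labelled female control 1, and in striatum 38 without female control 2, 39 without female cuprizone 1 and 41 without male cuprizone 2. The white matter effect of the integrated stress response list exceeded the cortical one by 0.44 (1.11 against 0.67, exact permutation p = 0.035, adjusted p = 0.438 over 25 lists), and for the myelin and mature oligodendrocyte list the difference was 0.05 (exact permutation p = 0.775).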

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

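Each test of the conflict between labels and sex transcripts was chosen after that result was seen. The results listed here are those whose cuprizone effect differed between females and males by a test of the difference itself.

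The cuprizone effect on haemoglobin transcripts was more negative in the libraries labelled female than in those labelled male. In white matter the interaction was -2.92 for Hbb-bs, -2.9 for Hba-a1, -2.85 for Hba-a2 and -2.74 for Hbb-bt. In the striatum it was -3.06 for Hba-a1, -3.05 for Hbb-bs, -2.75 for Hba-a2 and -2.73 for Hbb-bt. The erythrocyte list had a whole-section interaction of -2.21 (camera adjusted p = 3.7e-11, adjusted p = 0.38 with an estimated correlation). Whole-section Hba-a1 levels were 552 and 361 CPM in the female controls, 231, 185 and 130 in the female cuprizone sections, 187, 272 and 374 in the male controls, and 325, 657 and 565 in the male cuprizone sections. Within the prefixes, in fits of treatment alone whose arms differ in sex, Hba-a1 stood at -0.64 (FCG, adjusted p = 0.74) and 0.73 (LG, adjusted p = 0.0054).

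Rprm, which is expressed by deep cortical neurons, had a striatal interaction of 1.58 (SE 0.28, adjusted p = 0.015). Xist had a fitted striatal interaction of 7.4, which is no bound because most libraries labelled male and the library labelled female control 1 held 0 counts. With whole-section counts under 3 raised to that limit, the interaction of Xist was 7.04.

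Whole-section list medians differed between the sexes by the preset-correlation camera test for myelin and mature oligodendrocyte (-0.46), interferon response (-0.52), homeostatic astrocyte (-0.21), cholesterol synthesis (-0.12), inhibitory neuron (-0.28), immediate early genes (-0.81), choroid plexus (0.81) and Y-linked (-9.32). The Y-linked value is fitted and no bound, and with counts under 3 raised to that limit the list's median was -2.88. Several rest on single sections. With 1 section left out, the verdict changed in 7 of 11 fits for immediate early genes (-0.1 without female control 2), in 6 for cholesterol synthesis, in 6 for inhibitory neuron, in 5 for choroid plexus (0.19 without male control 2) and in 2 for interferon response (-0.09 without male cuprizone 1). It also changed in 2 for homeostatic astrocyte and in 2 for Y-linked, whose fitted value was -1.16 without the library labelled female control 1. None of these lists, nor the erythrocyte list, passed with an estimated correlation or with fry.

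The library labelled female control 1 held 0 counts of Xist and 319 of Ddx3y. Male RNA mixed into a female library is argued against, because at the level of female control 2 the library would hold 191 counts of Xist beside them. An exchange of labels within the series is also argued against, since 0 of the libraries labelled male had under 3 counts of Ddx3y. A single wrong label, or an animal with a Y chromosome but without Sry, may account for it and these cannot be told apart, because Sry had 0 counts summed over all libraries labelled male and so could not have shown the difference. Without both this library and male control 3, 12 genes passed in the averaged contrast instead of 47.

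The library labelled male control 3 held 205 counts of Xist. Over spots with the same barcode, its Xist counts multiplied with those of female control 2 summed to 346, against 130 if unrelated, and with those of the female cuprizone sections to 255, 36 and 20, against 203, 35 and 20.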

How the results depend on the processing

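Fits within each prefix (for the sexes under cuprizone within FCG only) and without both label-conflicting sections were added after the data were seen; all other alternatives were fixed before. Within a prefix treatment was the only factor and sex differs between the arms, so these are not the averaged contrast. No paired analysis was possible because the labels give no shared replicate numbers. Leaving out 1 female control leaves a lone section that is assumed to vary like the other groups. Depth limits low transcripts, since 0 counts allow 0.5247 CPM in the shallowest and 0.0366 CPM in the deepest whole section, and more within a region. The cause of the moves below was not tested, beyond fewer samples or genes where the alternative itself removes them. A count of genes was taken to stay when within a set ratio of its main value. A test was taken to stay when its call did, so its size could still move. Among the main results, 209 stayed in this sense under other settings, 44 moved and 10 were weaker, and with 1 section left out 182 stayed, 56 moved and 4 were stronger. Among single genes and the other lists, 1218 stayed, 279 were weaker, 8 stronger and 10 reversed under other settings, and 1674 stayed, 275 were weaker, 6 stronger and 3 reversed with 1 section left out. A result that had not passed could change its sign and still be counted as stayed. Averaged Tlr7, at -0.06 without female control 2, is 1 such case. No region share or difference between regions passed after adjustment under either other clustering, but shares moved. The white matter difference by treatment was 0.535 percentage points at resolution 1.0 and 1.101 with all variable genes, instead of 0.447, and that of hypothalamus -0.13 at resolution 1.0, instead of 0.294. With all variable genes no meninges region was named.

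The averaged count of 47 was 135 with DESeq2, 128 without a filter, 76 with the prefix as a covariate, 25 after thinning, 24 in FCG and 103 in LG sections, and 12 without both conflicting sections. Of the 47, all were among the calls of DESeq2 and of the prefix covariate, 14 among those in FCG, 34 in LG and 11 without both. The female count of 20 was 66 with DESeq2, 79 without a filter, 53 with only the groups compared, 42 with depth as a covariate and 37 with region-balanced sums. The male count of 4 was 54 with DESeq2 and 52 without a filter. The interaction count of 0 in edgeR (439 at an unadjusted p under 0.05) was 10 with DESeq2, 12 without a filter, 1 with the prefix and 1 with depth as a covariate, 4 with region-balanced sums and 7 without both sections. The count between the sexes was 11 in controls without both sections, instead of 0. Under cuprizone it was 333 with DESeq2, 177 without a filter, 36 with only the groups compared, 2 with the prefix, 103 with depth and 79 without both sections, instead of 14.

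The averaged list medians kept their values with an estimated correlation but lost their calls, at -0.5 for myelin and mature oligodendrocyte, 0.27 for integrated stress response, 0.63 for disease-associated microglia and 0.11 for reactive astrocyte, and the last 2 also with fry. Within LG these were 0.1 and 0.01, no longer past the threshold. The interaction of the myelin list (-0.46) lost its call with an estimated correlation and with fry. Among lists past the threshold, the LG fit of treatment alone had the other sign for antigen presentation (-0.04), complement (-0.02), erythrocyte (0.54) and Y-linked (1.41), where 2 male cuprizone sections stand against 1 female and 1 male control. Of lists not past it, homeostatic microglia (-0.13) and mitochondrially encoded (0.14) passed within LG against their pooled (0.14 and -0.02) sign. The prefix as a covariate reversed interferon response in females (-0.01), the interaction of immediate early genes (0.22) and, between the sexes under cuprizone, antigen presentation (-0.08) and immediate early genes (0.06). Both were also reversed in the FCG sections alone (-0.48 and 0.37), where 20 genes passed between the sexes. Also reversed were interferon response in females without female control 2 (-0.17), homeostatic microglia in males without male cuprizone 1 (-0.03, highest 0.24 without male control 3) and Y-linked between control sexes without female control 2 (0.37, lowest -9.05, fitted, without female control 1).

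The white matter count of 237 was 84 in FCG, 16 in LG and 115 without both sections. In female white matter it was 147 with the prefix, and in male 46. The white matter interaction count of 4 was 13 with DESeq2, 17 with the prefix and 10 without both. Cortex and hippocampus gave 79 with DESeq2, 55 with the prefix and 11 without both, instead of 33. Thalamus gave 0 in LG and 3 without both, instead of 22, and hypothalamus 0 in LG, instead of 3. Striatum gave 35 with DESeq2, 26 in FCG and 31 without both, instead of 70.

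With each section left out in turn (named where it moved a count most), counts ran from 20 (male control 3) to 66 averaged, also 25 without female control 2 or female cuprizone 3 and 30 without male cuprizone 2. Females ran from 11 (female control 1) to 55 (male cuprizone 1), males from 2 (male cuprizone 3) to 25 (male control 1), and the interaction from 0 to 9 (male control 3), also 6 without female control 2 or male cuprizone 1. Between the sexes the range was 0 to 6 (female control 1) in controls and 0 (female cuprizone 3, male cuprizone 2 or 3) to 169 (male cuprizone 1) under cuprizone. Averaged medians ran from -0.59 to -0.43 for myelin, 0.21 to 0.3 for stress, 0.26 (male cuprizone 1) to 0.75 for disease-associated microglia and 0.07 to 0.42 for reactive astrocyte. Interaction medians ran from -0.59 to -0.33 for myelin, 0.04 to 0.2 for stress (past the threshold without male control 2, at 0.11, or male cuprizone 1, at 0.2), -0.07 to 0.7 for disease-associated microglia (past it without female control 1, at 0.36, or male cuprizone 1, at 0.7) and -0.22 to 0.07 for reactive astrocyte. White matter ran from 62 (female control 2) to 299 averaged, 29 (female control 2) to 536 (male cuprizone 1) in females, 0 (male control 3) to 12 in males and 4 to 52 (male cuprizone 1) for the interaction. Cortex and hippocampus ran from 12 (male control 3) to 41, thalamus from 4 (male control 3) to 49 (female control 1), hypothalamus from 1 (female cuprizone 2 or male control 3) to 5 (female control 2 or any male cuprizone section) and striatum from 31 (male control 3) to 96.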

Other observations

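Tests of a wrong label of the LG cuprizone sections, of sex and prefix held apart, of a chance run of X genes, of escape from X inactivation and of an added copy of the X segment were chosen after those results were seen. The other tests were fixed before.

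Some genes are described here after their values were seen. Oxt, which encodes oxytocin, had 0.618, 0.739 and 0.453 CPM in the female cuprizone sections and 122, 167 and 398 in the male ones (-8.53, SE 1.85, adjusted p = 0.1). Among controls it ran from 1.16 CPM in the library labelled female control 1 to 306 in male control 3. Hcrt, the orexin precursor, had at most 1.09 CPM in the female cuprizone sections and ran from 1.12 to 309 among the male ones (-6.87, SE 2.09, adjusted p = 0.19). Neither passed. Within the hypothalamus region, Trh and Gal passed between the sexes under cuprizone at -2.61 (SE 0.4, adjusted p = 0.0077) and -3.07, and 86 genes passed in all. The prefix also differed between these groups. Hypothalamus took 14.686 to 17.386% of spots in the female and 17.504 to 20.45% in the male cuprizone sections. Whether the prefix or what was cut accounts for these differences was not tested. In the striatum Neat1, a nuclear long noncoding RNA, stood 1.38 higher in females (adjusted p = 7.5e-05).

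In male white matter Ttr fell by 2.16 on the log2 scale (SE 0.37, adjusted p = 0.0095), lost as a call without male control 2 or 3, at -1.44 and -2.28. Those 2 sections held 48 and 45 choroid plexus spots, against 10 in male control 1 and 10 to 13 in the male cuprizone sections. Thalamic falls in males included Esrrg, a nuclear receptor, at -1.22 and Enpp2 at -0.94. In female thalamus Cd52, a leukocyte surface protein, rose by 2.92 (adjusted p = 0.0036) and Serpina3n by 2.72 (adjusted p = 0.043). No female control matched the female cuprizone sections in both prefix and Xist, so these rises are not separated from either. Over the whole section, fits of treatment alone within FCG and LG gave 1.77 and 0.17 for Cd52 and 1.33 and 0.14 for Serpina3n.

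Disease-associated microglia and reactive astrocyte genes were lower in the LG than in the FCG cuprizone sections, by a median of 0.67 on the log2 scale over the 47 genes of both lists (SD over genes 0.88), and 41 of them were higher in the 4 FCG sections than in the 2 LG sections. Depth is argued against, since the difference was 0.72 over 45 genes after thinning to 1 total. A smaller share of white matter is likewise argued against, since the difference was 1.41 over 39 genes within white matter. That test holds only the share fixed and cannot show which parts of the white matter were cut. Region shares differed between the prefixes, so what was cut stays open. Controls labelled as cuprizone sections are argued against by the rise of Atf5 within LG, at 1.3. The male FCG section lay above the male LG sections by a median of 1.09 (SD over genes 1.06, 43 of 47 genes higher) and above the female FCG sections by 0.55 (SD over genes 0.41, 45 of 47), which goes against sex alone. Yet this rests on 1 section. Sex and a batch behind the prefix cannot be told apart, because 0 female cuprizone sections had the LG prefix and 1 male one had FCG, and either may contribute to the difference.

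A run of 7 neighbouring genes on chromosome X (167207093 to 169320374, mm10) was lower in the female than in the male cuprizone sections. It holds Tmsb4x, Tlr7, Prps2 (-0.84), Frmpd4, Msl3 (-0.88), Arhgap6 (-0.82) and Hccs, and was picked as the longest such run. Each of 1000 shuffles of the order of 12787 genes was therefore searched for its own longest run past 0.5 on the log2 scale, in either direction. A chance order of genes is argued against, since 0 shuffles had a run of 7 genes and the longest had 4. Escape from inactivation would raise the genes in females. The run was picked from genes lower in females by more than 0.5 on the log2 scale. Its median of -0.88 therefore had to lie below 0 and cannot test escape. The size of the male excess given next is also partly set by that choice. A candidate explanation is 1 more copy of the segment in animals with Y-linked transcripts, since males had 1.84-fold the female level in the median and the library labelled female control 1, which held such transcripts, lay nearer to the males for 3 of 3 called genes.

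Other splits of the sections were drawn for each count. In the averaged contrast 2 of 100 splits gave as many genes, the real one included (47 genes, highest other 149), and in the FCG sections 1 of 35 (24, highest other 14). In white matter the share was 2 of 100 (237, highest other 406) and in cortex and hippocampus 4 of 100 (33, highest other 519). It was 2 of 100 in thalamus (22, highest other 68) and in striatum (70, highest other 614). These shares are under 0.05, without adjustment over the tests. Except in FCG, some other split gave a larger count. Chance is thus made less likely and is not excluded. The share was above 0.05 for the number of lists past the threshold (7 of 100, 16 lists, highest other 18) and for hypothalamus (8 of 100, 3 genes, highest other 157). For males (2 of 10; 4, highest other 5), for male white matter (2 of 10; 8, highest other 55) and for the sexes under cuprizone (1 of 10; 14, highest other 1) the 10 splits are too few for a share under 0.05. The splits with several times the real count put all LG sections they included on 1 side, a structure of the samples. The averaged count was 76 with the prefix as a covariate, and fits of treatment alone called 24 genes within FCG and 103 within LG.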
